A study of Oryza sativa with 2 samples.

How the data were processed

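Polyadenylated RNA was measured by RNA sequencing in 2 libraries of whole 3-week-old seedlings of Nipponbare, the japonica rice cultivar whose genome serves as the reference for the species. Per the labels' protocols, the plants grew hydroponically in Yoshida nutrient solution under short days of 10 h light and 14 h dark at 800 μmol per square metre per second, and the libraries were made with an NEBNext Ultra kit and sequenced on an Illumina HiSeq instrument. The labels place both libraries in 1 group and number them 1 and 2. Nothing in the labels says whether the libraries came from separate plants or pools of plants, so the spread between them may be partly technical.

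The authors deposited 1 FPKM value (fragments per kilobase of transcript per 1000000 fragments) per locus and library, per the file headers. Cufflinks made the values, per the submitters' processing notes, which give no version. The aligner, the genome build, the gene annotation and whether counting used strand are not given in the sources used here. FPKM values are already divided by transcript length and by library depth, so a model of read counts was not applied to them. The values of a library summed to 670155 and 651935 FPKM, which shows that they were not scaled to a common total. The number of sequenced fragments is unknown. The ratio between the libraries of loci with very low values does carry their relative depth, because a locus with equal read numbers in both differs only by the depths. Loci at a mean of 0.001 to 0.5 FPKM were kept if above 0 in both libraries and at an absolute log2 ratio under 0.5. The estimate could not fall outside that range of ratios. The commonest ratio over these 940 loci put library 2 at 1.08 times the depth of library 1 (95% bootstrap interval over loci 1.06 to 1.09). This estimate assumes equal fragment lengths.

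The 38511 loci carry rice locus identifiers with no gene names or descriptions. The supplied reference table (assembly ASM3414082v1) shared 1 identifier with them, through a synonym. The 28 gene lists fixed before the data were examined therefore had 0 matched members, and no list was tested. Transcript lengths, exon numbers and GC content per identifier were not used here either, so the planned check of level against gene structure was void. In the naming convention of rice loci, the identifier holds the chromosome number and then a locus number that increases along the chromosome. Chromosome and order were read from it and were not checked against a genome. Chromosome coordinates are not given for this reason. The identifiers of 257 loci hold no chromosome number, and these loci were left out of every comparison along chromosomes.

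A locus was called expressed at a mean of at least 1 FPKM over the 2 libraries. Levels are given as the mean ± SD over libraries (n = 2), and ratios between libraries are on the scale of log2(FPKM + 1), which understates changes of loci with low values. With 1 library on each side, no test of single loci between the libraries exists and no p-value is given for one. The loci to be named were fixed before the data were examined as the 10 with the highest mean, and, at a mean of at least 10 FPKM, the 5 with the highest and the 5 with the lowest ratio. Identifiers are printed for the former and for 2 at each end of the latter, because identifiers without names say little.

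The comparisons along chromosomes were chosen after the data were seen. Shares of expressed loci per chromosome were tested with 10000 circular shifts of the expression calls around the ordered loci, which keeps neighbouring loci together, with Benjamini-Hochberg adjustment over the 12 chromosomes. The outer 20% of loci at each end of a chromosome were compared with the inner part by an exact sign-flip permutation test over the 12 chromosomes. Pairs of consecutive expressed loci that were both 2-fold apart between the libraries were counted against 10000 permutations of the ratios over expressed loci. All p-values are two-sided except those for counts of pairs and for counts of loci among 10 consecutive expressed loci. Those test for an excess. Loci are not independent replicates, so these tests describe the 2 libraries.

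The tests were checked on simulated data. The circular shift test on 38254 loci called a planted low chromosome in 47 of 100 runs and called 0.18% of unchanged chromosomes. It can therefore miss a difference of the size planted. The permutation test of pairs on 19169 expressed loci called 0% of 20 runs without clusters and 100% of 20 runs with 15 planted runs of 3 loci. The runs without clusters were permutations of the ratios, as in the test itself, so a low rate of calls there was built in. They could not show how the test behaves where neighbouring loci have similar levels. The depth estimate averaged -0.137 on the log2 scale over 20 simulated pairs of libraries on 38254 loci, against a simulated -0.138. The alternatives tried were other thresholds, pseudocounts, filters and scalings between libraries, and each library alone. The analysis used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.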

Results

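The transcriptome of wild-type Nipponbare seedlings was measured in 2 RNA-seq libraries, as the expression side of a study of N6-methyladenine in rice DNA and its relation to gene expression. The methylation data were not analysed here, and both libraries belong to 1 group, so the design implies a description of transcript levels and a comparison of the replicates. Each library listed FPKM values for the same 38511 loci. Sequencing depth was unknown beyond the ratio of the libraries, with library 2 estimated at 1.08 times the depth of library 1.

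About 50% of the listed rice loci were expressed in the seedlings. A mean of at least 1 FPKM was reached by 19187 loci, or 49.8% of those listed, with 19175 loci in library 1 and 18919 in library 2 (19047 ± 181, SD, n = 2). Both libraries reached 1 FPKM at 18143 loci, and 1808 loci did so in 1 library only. A further 12227 loci, 31.7% of the total, were listed at 0 in both libraries. At 4 loci, values were listed at 0 in library 1 and at 10 FPKM or more in library 2, reaching 76.8 FPKM, and 10 loci showed the opposite, reaching 31.2 FPKM in library 1. Whether such zeros are failed estimates or true low levels was not tested. The median locus above 0 stood at 5.67 ± 0.13 FPKM (SD, n = 2).

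A small number of loci carried much of the signal. The 60 loci at a mean of 1000 FPKM or more held 24.9% of the summed FPKM in library 1 and 24.1% in library 2. The 961 loci between 100 and 1000 FPKM held 31.4% and 30.8%, and the 8530 loci between 10 and 100 FPKM held 36.9% and 38.2%. The 100 loci with the highest means held 28.7% ± 0.7 (SD, n = 2), and the highest 10 held 10.1% ± 0.04 (SD, n = 2).

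The highest mean belonged to LOC_Os01g10400 on chromosome 1, at 9407 ± 246 FPKM (SD, n = 2 here and for the loci that follow). LOC_Os01g41710 on the same chromosome followed at 9240 ± 1766 FPKM, so these 2 loci differed by less than the spread between replicates. LOC_Osxxg00162, whose identifier holds no chromosome number, reached 8922 ± 615 FPKM. Chromosome 12 held 3 of the 10 highest loci: LOC_Os12g19381 at 8235 ± 270 FPKM, LOC_Os12g17600 at 7877 ± 2413 FPKM and LOC_Os12g02340 at 4608 ± 540 FPKM. LOC_Os12g17600 was the most variable of the 10, with 6171 FPKM in library 1 and 9584 FPKM in library 2, a ratio of 1.55. LOC_Os03g39610 reached 5941 ± 738 FPKM, LOC_Os09g17740 reached 4425 ± 245 FPKM, LOC_Os07g37550 reached 4282 ± 503 FPKM and LOC_Os02g10390 reached 4004 ± 289 FPKM. Of the 10 loci, LOC_Osxxg00162 and LOC_Os12g17600 were higher in library 2 and the other 8 were higher in library 1. The 1 identifier that the reference table paired with a gene, LOC_Os01g19850, is a gene with the synonyms KCC2 and OsCCC2, a cation-chloride cotransporter. Its level was 0.332 ± 0.192 FPKM (SD, n = 2), below the threshold for expression.

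The 2 libraries ranked the loci closely alike. Across the 19187 expressed loci, Pearson's r of log2(FPKM + 1) was 0.94 and Spearman's rho was 0.94. These values are across loci, which are not independent replicates, and carry no p-value. The number of loci above 0 with the same value in both libraries was 0, so the files are not copies of each other. The median log2 ratio of library 2 over library 1 was 0.02 with an SD over loci of 0.58, and 83.5% of expressed loci lay within 1.5-fold. A 2-fold difference was found at 1295 expressed loci, 6.7% of them, with 625 higher in library 2 and 670 higher in library 1. At 119 loci library 2 was at least 4-fold higher, and at 147 loci library 1 was. Requiring a mean of at least 5 FPKM lowered the number 2-fold apart to 720, of which 374 were higher in library 2 and 346 higher in library 1.

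**Figure D1:**
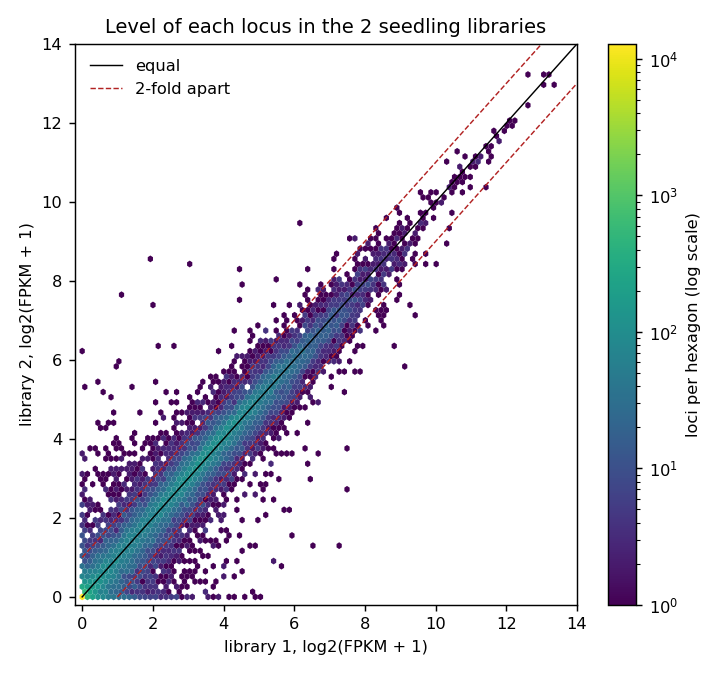
Level of every listed locus in library 1 (horizontal axis) and library 2 (vertical axis), both as log2(FPKM + 1), with colour giving the number of loci per hexagon on a log scale. The solid line marks equal levels and the dashed lines a 2-fold difference, outside which 1295 of the 19187 expressed loci lie.

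Differences between the replicates varied with level. The share of loci 2-fold apart was 11.3% at a mean of 1 to 2 FPKM, 8.9% at 2 to 5 FPKM and 4.6% at 10 to 20 FPKM. It was 5.0% at 20 to 50 FPKM and at 50 to 100 FPKM, 7.5% among the 910 loci at 100 to 500 FPKM and 5.4% at 500 FPKM or more. No test of these shares against level was made. The median log2 ratio was 0.06 at 10 to 20 FPKM (95% bootstrap interval over loci 0.05 to 0.07), -0.10 at 100 to 500 FPKM (-0.14 to -0.07) and -0.12 over the 111 loci at 500 FPKM or more (-0.15 to -0.07). Highly expressed loci were therefore slightly lower in library 2 relative to loci of middle level.

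The loci furthest apart between the replicates differed by far more than the SD of 0.58. LOC_Os07g37850 had 1.07 FPKM in library 1 and 204 FPKM in library 2, a log2 ratio of 6.63. LOC_Os10g05970 on chromosome 10 had 2.78 and 373 FPKM, a log2 ratio of 6.63. In the opposite direction, LOC_Os02g35610 had 159 FPKM in library 1 and 1.37 FPKM in library 2, a log2 ratio of -6.08, and LOC_Os03g12510 had 93.6 and 1.36 FPKM, a log2 ratio of -5.32. Of the 5 loci with the highest ratios at a mean of at least 10 FPKM, 3 lay close together on chromosome 10, at locus numbers 5950, 5970 and 6000. With 1 library on each side, none of these differences can be tested.

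Chromosome 10 held 2 stretches of neighbouring loci that differed between the replicates in opposite directions. At locus numbers 5720 to 6000, 10 expressed loci summed to 37.7 FPKM in library 1 and 859 FPKM in library 2, a 22.8-fold difference. The 3 highest of them held 787 of the 859 FPKM, and the other 7 summed to 27.5 and 72.0 FPKM. Of the 10, 6 were at least 2-fold higher in library 2 and 4 were not, and their log2 ratios had a median of 1.53 and a lowest value of -0.71. Permutations of the ratios reached 7 such loci among 10 consecutive expressed loci (permutation p = 0.0027 for 6 anywhere in the genome). At locus numbers 31510 to 31710, 10 expressed loci summed to 84.0 FPKM in library 1 and 19.6 FPKM in library 2, a 4.29-fold difference, with 7 at least 2-fold higher in library 1 and a median log2 ratio of -2.10. Both stretches were picked for loci 2-fold apart in 1 direction, so medians past a 2-fold difference follow from that choice. The SD of the log2 ratio was 0.76 on chromosome 10 and 0.50 to 0.63 on the other chromosomes. The value of chromosome 10 did not pass the circular shift test (adjusted permutation p = 0.098). It was 0.63 without the 2 stretches, but leaving out loci picked for large ratios lowers an SD by construction.

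**Figure D2:**
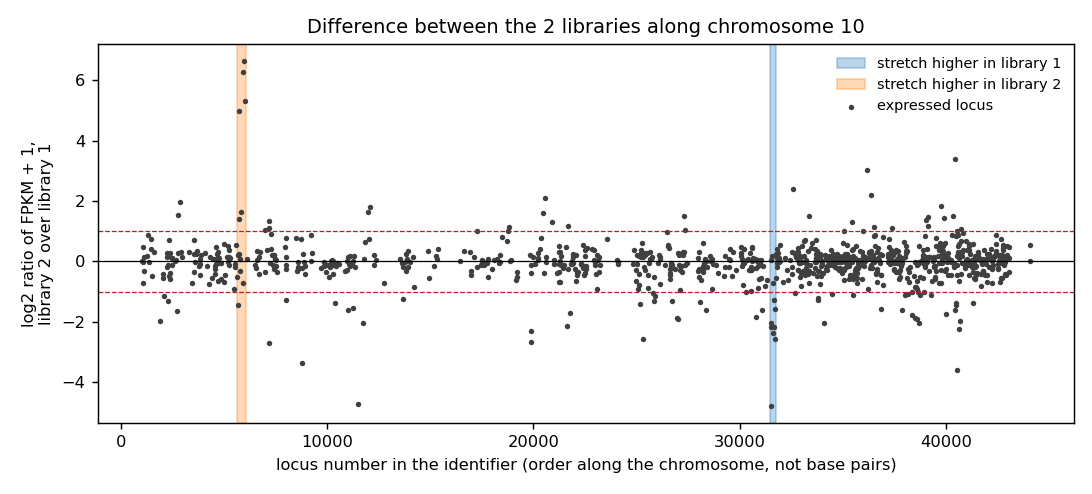
Log2 ratio of FPKM + 1, library 2 over library 1 (vertical axis), of each expressed locus of chromosome 10 by locus number (horizontal axis, order and not base pairs), with dashed lines at a 2-fold difference. The shaded bands mark the stretch at 5720 to 6000, which holds ratios up to 6.63, and the stretch at 31510 to 31710, with ratios down to -4.77.

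Chromosomes differed in the share of their loci that were expressed. Chromosome 3 had the highest share, 58.4% ± 0.2 (SD, n = 2), followed by chromosome 2 with 55.6% ± 0.2 and chromosome 1 with 54.7% ± 0.3. Chromosome 11 had the lowest, 36.3% ± 0.2, below chromosome 12 with 43.2% ± 0.8 and chromosome 10 with 43.3% ± 0.6. These shares were taken at 1 FPKM in each library on its own and averaged. On the mean FPKM, as used in the test below, they were 58.6% for chromosome 3 and 36.8% for chromosome 11. The median level was 2.81 FPKM on chromosome 3 and 0.119 FPKM on chromosome 11. The gaps between chromosomes 3 and 11 were far larger than the spread between replicates. That spread covers repeat measurement of the same loci and not the variation from 1 set of loci to another, so it does not test the gaps. The share of each chromosome was tested with circular shifts that keep neighbouring loci together, and the gap between 2 chromosomes was not tested. The adjusted permutation p was 0.69 for chromosome 3 and 0.42 for chromosome 11, and 0 of 12 chromosomes passed after adjustment, with 1 of them, chromosome 11, at an unadjusted p under 0.05 (0.035). This test called a planted low chromosome in 47% of simulated runs, so it can miss a difference. When loci were shuffled without regard to their neighbours, the adjusted permutation p was 0.0002 for both.

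Expression was more frequent in the outer parts of the chromosomes than in the inner part. The outer 20% of loci at each end were expressed at 54.5% ± 7.7 (SD over 12 chromosomes) and the inner loci at 45.2% ± 6.0, a mean difference of 9.4 percentage points (SD 6.2). The outer share was higher on 10 of 12 chromosomes, the exceptions being chromosomes 4 and 9, and the difference passed an exact sign-flip permutation test (p = 0.002, where the smallest possible is 0.0005). The 2 ends were then taken separately, and the difference between them was not tested. The last 20% of loci were above the inner part by 13.6 percentage points (SD 6.6, higher on 11 of 12 chromosomes, exact permutation p = 0.00098), while the first 20% were above it by 5.1 points (SD 12.3, higher on 9 of 12), which did not pass (exact permutation p = 0.17). Over all chromosomes, the loci were divided by order into 10 equal classes. The share at 1 FPKM or more was taken in each library on its own and averaged. It was 53.0% ± 0.6 (SD, n = 2 libraries) in the first class, 49.8% ± 0.7 in the second and lowest in the fourth, at 39.5% ± 0.5. It was 50.3% ± 0.4 in the seventh class, 55.3% ± 0.5 in the eighth, above the first class, and 60.9% ± 0.4 in the last. In windows of 1000 locus numbers with at least 20 loci, the share on the mean of both libraries ranged from 11.1% to 82.9%. The lowest window was at locus numbers 7000 to 7999 of chromosome 4, with 3 of 27 loci expressed, and the highest at 69000 to 69999 of chromosome 1, with 34 of 41.

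**Figure D3:**
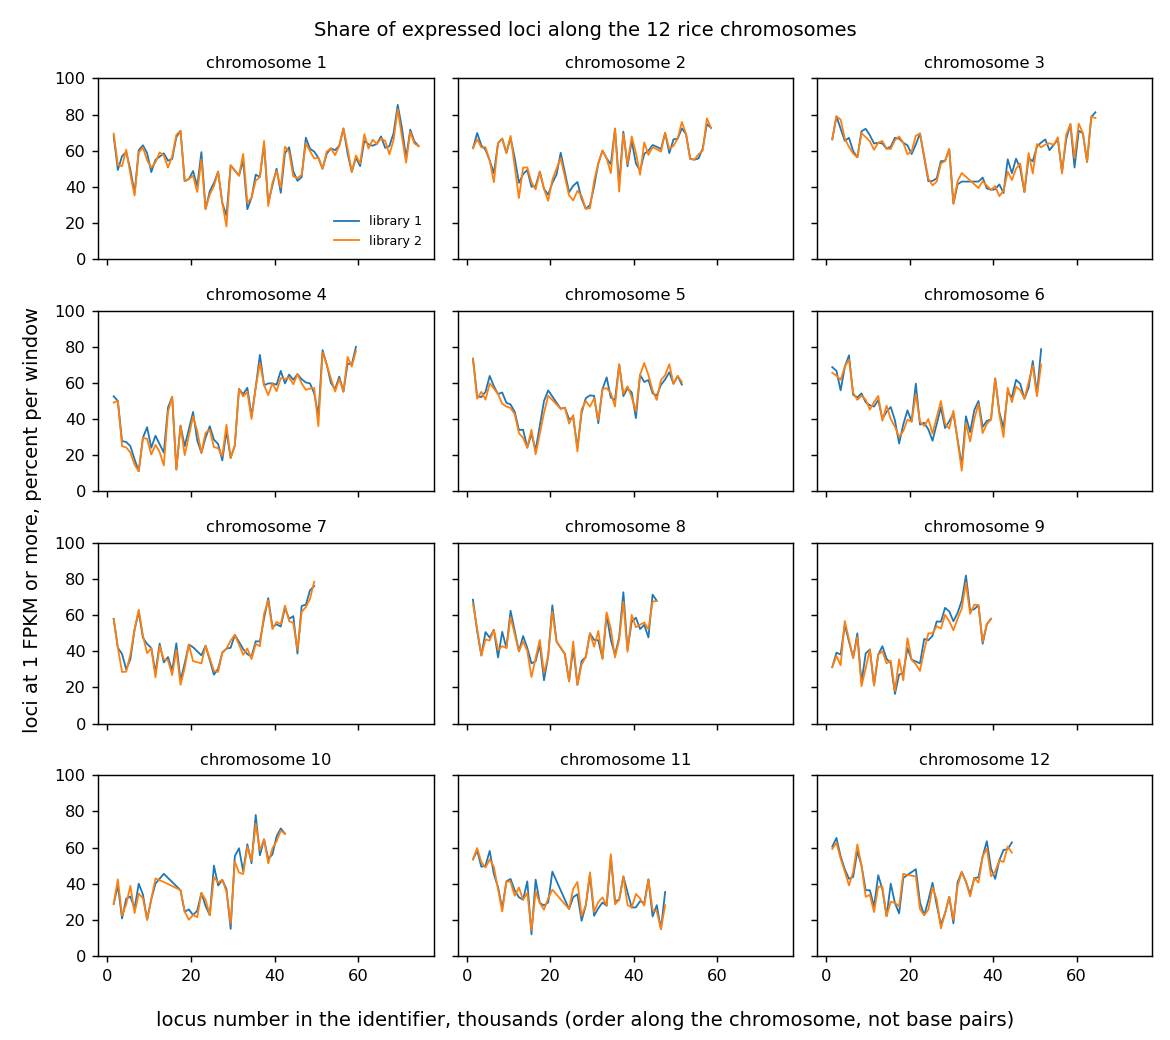
Percent of loci at 1 FPKM or more (vertical axes) in windows of 1000 locus numbers along each of the 12 chromosomes (horizontal axes, locus number divided by 1000, which gives order and not base pairs), with 1 line per library. The lines of the 2 libraries run close together, and range from 11.1% on chromosome 4 to 85.4% in library 1 on chromosome 1.

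Loci of similar level lay next to each other more often than chance gives. Spearman's rho between the levels of consecutive loci was 0.22, against a highest value of 0.02 in 1000 permutations. It was 0.13 for loci 3 apart and 0.08 for loci 10 apart, and stayed at 0.06 for loci 200 apart.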

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

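Alternatives were set before the data were examined, except those for results along chromosomes, which were added after the data were seen. The number of expressed loci stayed between 13303 (threshold of 5 FPKM) and 24365 (threshold of 0.1 FPKM), and was 20411 with libraries rescaled to a common sum of 1000000. Pearson's r was 0.91 with a pseudocount of 0.1, 0.98 with no filter on low values and 0.92 with a filter at 5 FPKM. The 1295 loci 2-fold apart became 720 with that filter, which tests fewer loci (13303), 1797 with a pseudocount of 0.1, 1622 with libraries rescaled to a common sum, 1482 with no filter and 1286 with median-ratio scaling. The share of them higher in library 2 was 48.3% and ranged from 45.9% (median-ratio scaling) to 51.9% (filter at 5 FPKM), where the balance turned toward library 2, and the median log2 ratio of 0.02 became 0.06 with libraries rescaled to a common sum and -0.0004 with median-ratio scaling, which centres it by construction. The share of FPKM in the top loci was 10.1% for 10 in place of 100. Shuffling loci without regard to neighbours left the shares of chromosomes 3 and 11 at 58.6% and 36.8%, as on the mean of both libraries, but took both past the threshold (adjusted permutation p = 0.0002), and the adjusted p under the other settings ranged from 0.29 to 0.79. The excess of expressed loci in the outer parts of chromosomes passed its exact permutation test under the 5 other thresholds, widths and single libraries, at 7.3 to 10.8 percentage points, and at the end with the highest locus numbers alone (13.6), but not at the start alone (5.1, exact permutation p = 0.17). Same-direction neighbouring pairs numbered 188 with a pseudocount of 0.1 and 67 with a filter at 5 FPKM, which were 2.23 and 3.44 times the permutation mean. Each library alone left the counts of expressed loci, the share of the top 100 (28.4% without library 1, 29.3% without library 2) and the chromosome shares on the same side. The alternatives on gene lists, gene structure and organelle-encoded genes were not run, because identifiers could not be matched to annotation. No paired analysis was possible because there is only 1 group. Unknown depth limits what can be said of loci under 1 FPKM.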

Other observations

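All tests in this part were chosen after the data were seen, and the tests of pairs 3 apart and of the outer parts of chromosome 11 had their predictions written before their results. The replicates differed in groups of neighbouring loci. In 6 stretches, at least 5 of 10 consecutive expressed loci were 2-fold or more apart in the same direction, 5 of them higher in library 1. The highest count was 7 higher in library 1, where 10000 permutations reached 6 (permutation p = 0.0001). It was 6 higher in library 2, where they reached 7 (permutation p = 0.0027). Stretches with a count of 5 or 6 thus lay within the range that permutations reached. The bounds given are those of the outermost loci 2-fold apart. Chromosome 10 held 2 of the stretches. On chromosome 4, 7 of 10 consecutive expressed loci were at least 2-fold higher in library 1, at numbers 54210 to 54310, and these 7 summed to 1106 FPKM in library 1 and 359 FPKM in library 2. On chromosome 7, 6 of 10 were, at numbers 3279 to 3730, with sums of 249 and 57.1 FPKM. The remaining stretches were at 37940 to 38010 of chromosome 11 and 36770 to 36880 of chromosome 12, with sums 2.31-fold and 3.88-fold higher in library 1. In the former, 5 of 8 expressed loci were at least 2-fold higher in library 1, with log2 ratios from -3.09 to 0.33 and a median of -1.31. In the latter 5 of 7 were, with log2 ratios from -3.22 to 1.17 and a median of -1.85, so that it also held a locus over 2-fold higher in library 2. Each stretch was picked and bounded by loci 2-fold apart in 1 direction, so a median past a 2-fold difference follows from that choice. No gene names were matched to these loci.

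Over the whole genome, 125 pairs of consecutive expressed loci were 2-fold apart in the same direction, 83 of them higher in library 1 and 42 in library 2. Chance placement is argued against, because 10000 permutations averaged 43.6 such pairs and reached 73 at most (p = 0.0001, the smallest they can give). Reads assigned to different neighbouring copies in each library would give pairs apart in opposite directions, and these numbered 48, an excess of 4.4 over the permutation mean against 81.4 for same-direction pairs. Reads shared by adjoining gene models would not reach loci 3 apart, yet 80 same-direction pairs stood 3 apart, above the highest permutation of 70, so such reads cannot be the whole source. Copies elsewhere in the genome, differences between the plants and coordinated expression of neighbouring genes stay open, since no sequence was used and the design has 1 group, so no biological explanation was tested.

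Chromosome 11 had the lowest share of expressed loci, which did not pass the circular shift test after adjustment. It held 0 of the 10 highest loci and 5.8% and 5.5% of the summed FPKM in libraries 1 and 2. It held 13 of the 100 loci with the highest means, against 6.9 given by its number of loci (adjusted p = 0.23 by circular shift permutations, unadjusted 0.019), so this excess does not pass correction. A candidate explanation for the low share, a larger silent inner part alone, was tested on the outer loci. These were expressed at 40.2% on chromosome 11 and at 46.5% to 66.0% on the other 11 chromosomes, while its inner loci stood at 34.6% against 36.6% to 53.7%. The outer share of chromosome 11 pooled unlike ends. In windows of 1000 locus numbers it was 46.7% to 57.0% at numbers 1000 to 6999. At numbers 40000 to 47999 it was 14.8% to 42.4%, so the low outer share came mainly from the far end. The prediction written beforehand took an outer share below every other chromosome as evidence against this explanation, and that was found. It set no margin. The outer share lay below the lowest of the others by less than the SD of 6.5 over those chromosomes. Chromosome 11 was also picked as lowest over all its loci, outer ones included, so a low outer share partly follows from that choice. The outer part was a fixed 20% of loci at each end, so a larger silent inner part could reach into it. The test therefore cannot decide on the explanation.

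The form of the values differed between loci. Among 24103 loci above 0 in both libraries, 6393 in library 1 and 6405 in library 2 had values with more than 6 significant digits, and 5509 had them in both. This overlap was 2.79 times that of chance within 20 classes of level. Sums of several Cufflinks records at loci with several transcripts would give such an overlap. Any other fixed property of a locus that affects the form of its value would too. Transcript numbers were not used, so the source stays open. Loci with long values in both libraries had a median of 10.7 FPKM, against 5.17 FPKM for loci above 0 with shorter values in both. Over the expressed loci of each kind, the SD of the log2 ratio was 0.40 and 0.61. Values under 0.001 FPKM but above 0 were listed at 74 loci in library 1 and 72 in library 2, down to 6e-231 FPKM. The 257 loci without a chromosome number had 18 expressed members, and the 2 highest held 95.03% of the group's FPKM in library 1 and 94.6% in library 2.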
